A study of Mus musculus with 24 samples.

How the data were processed

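Gene expression in mouse reticulocytes was measured on 24 Illumina mouse bead arrays, 3 wild-type and 5 mutant at each of 0, 12 and 24 h of culture. Groups were taken from the labels, which state the genotype and the time of each sample. A key supplied by the authors writes 15 h where the labels write 12 h, and the labels' time was kept. Per the labels, total RNA was isolated with a column kit, amplified and labelled with biotin. The deposited unnormalized table gives a signal intensity per probe, with no normalization or background subtraction by the authors, and a detection p-value per probe and array from the deposited table, in steps of 1/798. The authors' processed values are on a linear scale, and on each array they are a straight-line function of the raw intensity (largest residual 0.0145). The method behind them is not given in the sources used here. Their column medians were 93.3 to 108. No aligner was used, and a genome build is not given in the sources used here.

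The tables hold 25697 probes, of which 23978 carry a gene name and 1719 do not, with 16593 distinct names. Names of 23962 probes matched the reference table of mouse genes, and none was changed. Probes naming several genes numbered 0. The choices that follow were made before the data were examined unless stated otherwise. Intensities were background-corrected with the normexp model, with negative-control levels inferred from the detection p-values, an offset of 16 was added, and arrays were quantile-normalized and put on a log2 scale (limma neqc). A probe was kept if its detection p was below 0.01 in at least 3 of the 24 arrays, which left 6312 probes, 5918 of them named. The probe with the highest mean was taken for each name, which gave 4846 genes, 845 of them with several probes. In all 24 arrays 235 probes were detected. The share detected per array, higher in mutant, sets which genes could be measured and may favour those higher in mutant.

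A linear model with 6 group means was fitted with limma (version 3.58.1, R 4.3.3) with an intensity trend in the variance, and p-values were adjusted per comparison by Benjamini and Hochberg, with a threshold of 0.05. The comparisons were mutant minus wild type at each time, each pair of times within a genotype, and the difference between genotypes in the change from 0 to 12 h and from 0 to 24 h. Values are log2 differences ± SE from this model, and group means ± SD. Shares of detected probes were compared by exact permutation of the arrays and, for paired arrays, by exact sign changes within pairs. Of 31 gene lists written in advance, the 29 with at least 5 tested genes were tested with camera (limma) at a preset correlation of 0.01, and again with an estimated correlation. Camera sets a list against all other tested genes. A list called up or down thus moved relative to these, and its own level need not have moved that way. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

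The genes named follow a rule set in advance. For each genotype comparison and each change from 0 h they come from the 8 largest rises and the 8 largest falls, not all of which are named. These were ranked among genes past the threshold whose groups do not overlap and whose probe is detected in every array of at least 1 group. For each list described they are up to 4 members with the smallest p, and for each interaction the 6 genes with the smallest p, besides 10 genes of red cell maturation and autophagy, of which Atg7 had no probe past the filter. By chance the groups of a gene would not overlap in 10% of cases with 3 arrays against 3 and in 3.57% with 3 against 5. Where 1 group was not above background on any of its arrays, a change is given as a lower bound: the mean of the bright group against the mean of the dim group, with each dim array set to the lowest signal of its probes above background or to the probe's own signal, whichever was higher. Where this gave no bound, no fold is given.

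The method was tested on simulated data of the same size, with independent normal values from 1 mean and 1 residual spread per gene. Changes of 1 log2 unit were recovered in 50 to 83% of genes and changes of 2 in 91 to 100%, with 4 to 14 false calls per comparison. The simulation held no array effects, no correlation between genes and no difference in spread between groups. These rates thus do not describe the real arrays, where setting mutant 0 h arrays 3, 4 and 5 against the other 0 h arrays called 2441 genes. Whether replicate numbers mark the same animal was checked by correlating residuals of arrays with the same number. They correlated at 0.31 to 0.51 between 12 and 24 h in wild type, at 0.18 to 0.67 in mutant, and at 0.11 to 0.40 between 0 and 12 h in mutant. These arrays were treated as paired in the tests of sign changes. In mutant the pairing is uncertain, since arrays 2, 4 and 5 from 0 to 12 h and 3 and 5 from 12 to 24 h correlated more with another number. From 0 to 12 h in wild type (0.003 to 0.10), from 0 to 24 h (0.03 to 0.09 in wild type, -0.09 to 0.33 in mutant) and between genotypes (-0.46 to 0.25) the correlations were low or of mixed sign. Those arrays were not treated as paired in these tests, although from 0 to 24 h all but mutant array 5 correlated best with their own number.

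Alternatives were: no background correction, median centring in place of quantile normalization, the authors' processed values, no filter, only probes detected in all 24 arrays, the mean of a gene's probes, array weights, a fit of only the groups compared, animal blocks, an estimated correlation for the lists, a detection p below 0.05, and leaving out each array in turn. The probe chosen for each gene was kept under the other scalings. Unnamed probes past the filter, 394, were counted but not described.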

Results

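Gene expression was measured in mouse reticulocytes, the young red cells that leave the bone marrow without a nucleus and lose their RNA, ribosomes and mitochondria as they mature. Blood rich in reticulocytes was kept in culture, and total RNA was taken at 0, 12 and 24 h. The labels name a wild-type and a mutant group of adult male C57BL/6J mice. They do not name the mutated gene, so the level of the targeted gene could not be used to check them. Each genotype had the same number of arrays at each time, 3 for wild type and 5 for mutant, which gave 24 Illumina mouse bead arrays in 6 groups. The design text calls them biological replicates. The number of arrays limits the precision of every value, most of all in the wild-type groups.

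Few probes were above background. On average 3.46% ± 1.23 (SD, n = 3) of the 25697 probes were detected on the wild-type arrays at 0 h, 5.72% ± 0.85 at 12 h and 7.32% ± 0.39 at 24 h. The mutant arrays detected 9.89% ± 5.20 (SD, n = 5), 20.9% ± 5.91 and 14.5% ± 3.13. The mutant mean was higher by 6.43 percentage points at 0 h (exact two-sided permutation p = 0.0714, Benjamini-Hochberg adjusted over 9 comparisons 0.113), by 15.2 at 12 h (exact p = 0.0357, adjusted 0.107) and by 7.14 at 24 h (exact p = 0.0357, adjusted 0.107). The smallest exact p that 3 arrays against 5 can give is 0.0357. Between times the share in wild type moved by 2.26, 1.60 and 3.86 points from 0 to 12 h, 12 to 24 h and 0 to 24 h, each with an exact p of 0.1, the smallest that 3 against 3 can give. At a detection p below 0.05 the wild-type change from 12 to 24 h turned to -0.31 points. In mutant arrays the share moved by 11 (exact p = 0.0159, adjusted 0.107), -6.45 (0.0635, adjusted 0.113) and 4.57 points (0.151, adjusted 0.151). None of the 9 comparisons passed after adjustment. Within pairs of arrays with the same replicate number, the share rose in all 5 mutant pairs from 0 to 12 h and fell in all 5 from 12 to 24 h (exact two-sided p from sign changes = 0.0625 each, the smallest that 5 pairs can give). It rose in all 3 wild-type pairs from 12 to 24 h (exact p = 0.25, the smallest that 3 pairs can give). The median raw signal was 132 to 298 on the 0 h arrays and 38.7 to 44.7 on the later ones. Normalized values of replicate arrays correlated across genes at 0.764 to 0.827 in wild type at 0 h, at 0.782 to 0.972 in mutant at 0 h, and at 0.918 to 0.992 in the other 4 groups.

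**Figure D1:**
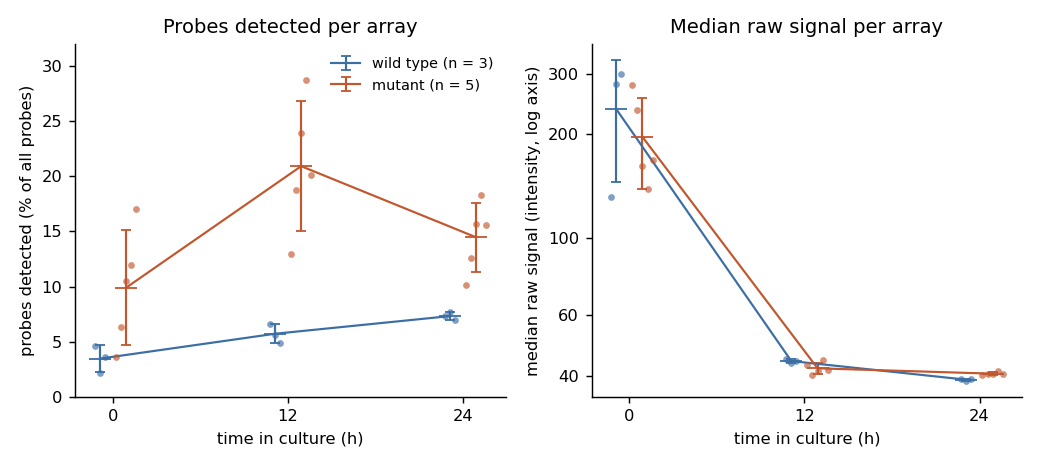
Probes detected as a percentage of all probes (left) and median raw signal on a log axis (right) against time in culture, with 1 point per array, lines joining group means and bars of 1 SD, for wild type (n = 3 per time) and mutant (n = 5). Mutant means were 9.89%, 20.9% and 14.5% of probes against 3.46%, 5.72% and 7.32% in wild type, and the 0 h arrays had median signals of 132 to 298.

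The comparison of genotypes at 0 h asks how freshly collected mutant reticulocytes differed from wild type. Of 4846 genes tested, 2060 differed, 1653 higher and 407 lower in mutant. Srp14, a subunit of the signal recognition particle, was at least 15.5-fold higher (limma adjusted p = 3.7e-16). Odc1, the rate-limiting enzyme of polyamine synthesis, was at least 5.35-fold higher (5.8e-10). Ncoa4, the receptor that carries ferritin to autophagosomes, was lower by -5.49 ± 0.29 log2 units (SE, adjusted p = 7.4e-13; 5.15 ± 0.38, SD, n = 5, against 10.64 ± 0.22, n = 3), and was detected on 1 of the 5 mutant arrays. Gclm, a subunit of the enzyme that starts glutathione synthesis, was lower by -4.15 ± 0.31 (4.4e-10), detected on 3 of 5 mutant arrays. Ube2o, a ubiquitin-conjugating enzyme that acts on ribosomal proteins in reticulocytes, was lower by -3.80 ± 0.19 (2.1e-13).

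Among the other largest differences at 0 h, the RNA-binding protein Hnrnpm was higher by 4.79 ± 0.42, Lyz1 by 4.79 ± 0.71 (its sequence is close to that of Lyz2, so its signal is uncertain) and Smim7 by 4.37 ± 0.38. The chaperone Hspa8 was at least 5.11-fold higher. The membrane protein Paqr9 was lower by -5.56 ± 0.28, the histone chaperone Anp32e by -4.22 ± 0.27 and the spindle protein Nusap1 by -3.73 ± 0.40, where a second Nusap1 probe differed by 0.01. Hnrnpm, Lyz1 and Smim7 were detected on 1 of 3 wild-type arrays, Paqr9 on 1 of 5 mutant arrays, and Anp32e and Nusap1 on 3 of 5. Genes of red cell maturation that were chosen beforehand moved apart. Tfrc, the transferrin receptor that maturing reticulocytes shed, was higher by 3.65 ± 0.69 (adjusted p = 0.00021), but differed by 1.66 (0.17) without wild-type arrays 2 and 3. That left 1 wild-type array at 0 h, which was assumed to vary like the other groups. Tfrc, Ulk1 and Sqstm1 were detected on 1 of 3 wild-type arrays at 0 h, and the last 2 on 3 of 5 mutant arrays. Alas2, which starts heme synthesis in red cells, was lower by -0.16 ± 0.04 (0.0041), with the call lost without those 2 arrays (-0.14, 0.13), with the authors' processed values (-0.37, 0.49) and with array weights (-0.12, 0.42). Bnip3l, the receptor that marks mitochondria for autophagy, was lower by -0.25 ± 0.10 (0.039). The call of Bnip3l was lost without any 1 of the 3 wild-type arrays or of mutant arrays 2, 3 and 5 at 0 h (adjusted p 0.052 to 0.10), under median centring (0.084), without the filter (0.066) and with array weights (0.48). It was also lost with fewer 0 h arrays (0.078 to 0.28), and the value turned to 0.08 with the authors' processed values. Gabarapl2, an autophagosome protein not above background in wild type, was higher (1.6e-05). Values did not pass for Ulk1, the kinase that starts autophagy (-0.88 ± 0.36, adjusted p = 0.056; another probe 0.21), the autophagy receptor Sqstm1 (-0.01 ± 0.50, 0.99), the autophagosome protein Map1lc3b (not above background in either genotype, 0.063), the anion exchanger Slc4a1 (-0.31 ± 0.22, 0.26) and alpha-globin Hba-a1 (-0.02 ± 0.05, 0.70). Hba-a1 shares its sequence with a near-identical copy and lies at the top of the scale that quantile normalization sets, so its values cannot show a difference. Single 0 h arrays decided several of these results. Ulk1 passed without wild-type array 3 (-1.42, 0.0033) or 2 (-1.05, 0.0497) and without mutant 12 h array 1 (0.044). Sqstm1 was 0.92 (0.079) without wild-type array 1, -0.67 (0.31) without array 3 and -1.87 (0.013) without arrays 2 and 3. Slc4a1 passed without mutant array 1 (-0.49, 0.036), and was 0.36 (0.54) with the authors' processed values. Map1lc3b passed without wild-type array 3 (0.047) or mutant array 2 (0.021) or 4 (0.037), without background correction (0.025) and with the authors' values (0.012).

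Markers of B cells stood apart from the other gene lists at 0 h. Of 17 tested B cell markers, 15 were higher in mutant and none lower (15 and 0 adjusted over the list alone), with a median of 2.15 and a camera adjusted p of 0.000405 (adjusted p = 0.92 with an estimated correlation). They included H2-Ab1 (4.18 ± 0.45, adjusted p = 1.2e-07), H2-Eb1 (at least 4.31-fold) and Cd74 (3.75 ± 0.52), which present antigen on B cells and other leukocytes, and Fcmr, the receptor for IgM (4.24 ± 0.59). H2-Ab1, Cd74 and Fcmr were detected on 1 of 3 wild-type arrays. Of 15 ubiquitin enzymes of maturing red cells, 3 were higher and 5 lower (median -0.46, camera adjusted p = 0.0391, and 0.92 with an estimated correlation), a call that median centring ended (adjusted p = 0.85) and the authors' processed values too (0.083). It was also lost without wild-type array 1 (0.095) or 2 (0.070) or mutant array 3 (0.053) or 5 (0.093). Rnf123, a ubiquitin ligase not above background in wild type, went the other way (higher, adjusted p = 0.00078), as did the ubiquitin-conjugating enzyme Ube2l6 (0.38 ± 0.09, 0.0027), and both calls were lost with the authors' processed values (0.059 and 0.057).

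Other lists were not called at 0 h, although many members were. Of 60 genes of oxidative phosphorylation 27 were higher and 7 lower (median 0.65, camera adjusted p = 0.745), of 54 cytosolic ribosomal proteins 23 and 5 (0.44, 0.327), and of 35 proteasome subunits 21 and 4 (0.93, 0.221). Of 42 translation factors 23 were higher and 1 lower (0.72, 0.131), of 53 mitochondrial ribosomal proteins 22 and 1 (0.38, 0.478) and of 18 lysosomal genes 10 and 0 (0.71, 0.0723). Under median centring 7 lists were called, among them ribosomal proteins, oxidative phosphorylation and lysosome. Leaving out single 0 h arrays also led camera to call some of these. They were ribosomal proteins without wild-type array 3 (adjusted p = 0.022), translation factors without wild-type array 1 (0.042) and lysosome without wild-type array 3 (0.045) or mutant array 2 (0.044). Markers of other blood cells moved with these groups: 8 of 14 neutrophil markers were higher and none lower (median 1.19, adjusted p = 0.696), among them S100a9 (3.55 ± 0.64, adjusted p = 0.00013, detected on 1 of 3 wild-type arrays, not passed with 1 wild-type array left, without arrays 2 and 3, 1.71, 0.11). Of the others, 11 of 15 T cell markers were higher and 1 lower (0.83, 0.219), with Cd3d at least 1.76-fold higher, and 5 of 11 monocyte and macrophage markers were higher and 0 lower (0.37, 0.429).

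Calls at 0 h were 80.2% higher in mutant, against 49.8% under median centring and 91.1% with the authors' processed values. Their number was 593 when only the 0 h groups were fitted, 1286 without wild-type arrays 2 and 3 (1 wild-type array left), 1183 among the 4 arrays of high background and 3334 without the filter on detection. Over all tested genes the median difference was 0.26 log2 units with the main setting, 0.16 without background correction, -0.10 under median centring and 0.17 with the authors' values. At 12 h these medians were 0.29, 0.16, -0.15 and 0.09, and at 24 h 0.17, 0.11, -0.11 and 0.16, so a small difference has no firm sign.

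At 12 h, 2432 genes differed between genotypes, 1660 higher and 772 lower in mutant. Srp14 was again far higher, at least 29.3-fold (adjusted p = 7.8e-15), and the translation factor Eif5 was higher by 2.55 ± 0.11 (6e-15; 14.14 ± 0.12, SD, n = 5, against 11.59 ± 0.07, n = 3), where a second Eif5 probe differed by 0.94. Ncoa4 was lower by -4.73 ± 0.29 (1.4e-11), Gclm by -3.98 ± 0.31 (1.1e-09) and Ube2o by -3.82 ± 0.19 (2e-13).

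The other largest differences at 12 h were lower values of Paqr9 (-5.05 ± 0.28), Anp32e (-4.25 ± 0.27) and the membrane scaffold Mpp1 (-3.42 ± 0.41), and of the retinaldehyde dehydrogenase Aldh1a1 (at least 21.4-fold) and the vesicle protein Syngr1 (at least 10.4-fold). Higher were Hnrnpm (2.93 ± 0.42), Prr13 (2.48 ± 0.31), Lyz1 (2.45 ± 0.71) and Odc1 (2.35 ± 0.35). The calls of Eif5, Prr13 and Lyz1 did not pass with the authors' processed values (adjusted p = 0.076, 0.058 and 0.059), and that of Lyz1 not without wild-type 12 h array 2 (2.07, 0.053). Of the genes chosen beforehand, Sqstm1 was lower by -2.37 ± 0.50 (adjusted p = 0.00096) and Ulk1 by -1.39 ± 0.36 (0.0047). Tfrc was higher by 2.06 ± 0.69 (0.019), a call that was lost without wild-type 12 h array 2 (2.08, 0.053) or 3 (2.01, 0.066), with the authors' values (1.10, 0.11) and without the filter (0.051). Alas2 was higher by 0.29 ± 0.04 (1.6e-05) but lower under median centring (-0.28) and with the authors' values (-1.01). Slc4a1 (-0.08 ± 0.22, 0.79), Hba-a1 (0.04 ± 0.05, 0.49), Bnip3l (-0.02 ± 0.10, 0.88), Map1lc3b (not above background in wild type, 0.38) and Gabarapl2 (0.56 ± 0.26, 0.071; another probe -0.35) did not pass. Slc4a1 and Bnip3l were called lower under median centring (-0.96, 0.015 and -0.70, 0.0059) and with the authors' values (-1.67, 0.0043 and -1.43, 0.0063), and turned to 0.12 each without wild-type 12 h array 1 (Slc4a1) or 3 (Bnip3l). Gabarapl2 passed without mutant 12 h array 4 (0.70, 0.035), without the 0 h arrays (0.029) and under median centring (0.00032). With array weights Slc4a1 (-0.31, 0.0027) and Map1lc3b (0.00046) passed, and Hba-a1 was -1.09 (0.039) with the authors' values.

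Of the 15 ubiquitin enzymes, 7 were lower at 12 h and 1 higher (median -0.42, camera adjusted p = 0.00498, and 0.817 with an estimated correlation), among them Ube2o, Ube2e3 (-2.41 ± 0.40) and Fbxo7, part of a ubiquitin ligase (-1.59 ± 0.27). Of 60 oxidative phosphorylation genes 14 were lower and 11 higher (median -0.08, adjusted p = 0.0349, and 0.94 with an estimated correlation), a call that ended under median centring (0.46) and without wild-type 12 h array 1 (0.10) or mutant 12 h array 4 (0.054). Lower members were the complex I subunit Ndufa1 (-3.31 ± 0.27), the complex III subunit Uqcrh (-1.85 ± 0.18) and the ATP synthase subunit Atp5b (-1.75 ± 0.19). Of 17 B cell markers 14 were higher and 0 lower (16 and 0 adjusted over the list alone; median 1.16, adjusted p = 0.00614, and 0.94 with an estimated correlation), including H2-Ab1 (2.43 ± 0.45), H2-Aa (1.92 ± 0.44, detected on 2 of 3 wild-type arrays) and Cd37, which was not above background in wild type and whose call was lost with the authors' values (0.29, 0.052). Neutrophil markers were higher in 7 of 14 (0.85, adjusted p = 0.301), S100a9 by 2.58 ± 0.64. T cell markers were higher in 9 of 15 with 1 lower (0.70, 0.301), monocyte markers in 6 of 11 with 1 lower (0.47, 0.317) and platelet markers in 7 of 14 (0.99, 0.152). The platelet list was called without wild-type array 3 of 12 h (0.0020) or of 24 h (0.031). Of 20 genes of the autophagy machinery 8 were higher and 4 lower (0.39, 0.874), and of 10 mitophagy regulators 3 and 2 (0.00, 0.657).

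The share of higher calls at 12 h was 68.3%, against 42.5% under median centring and 27.4% with the authors' processed values, which called 1172 genes. The count was 1310 without wild-type 12 h array 3, 1541 without array 2 and 4009 with array weights.

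At 24 h, 813 genes differed, 417 higher and 396 lower in mutant. Srp14 was higher by 3.20 ± 0.23 (adjusted p = 1.1e-09; 10.80 ± 0.14, SD, n = 5, against 7.60 ± 0.12, n = 3). Lower were Anp32e (-3.44 ± 0.27, 2.5e-09), Gclm (-3.12 ± 0.31, 1.4e-07), Ndufa1 (-3.01 ± 0.27, 4.6e-08) and Paqr9 (-2.97 ± 0.28). Ube2o was lower by -1.0 ± 0.19 (0.00067; 13.07 ± 0.12 against 14.07 ± 0.04). Higher were Glo1, which clears methylglyoxal (2.62 ± 0.44), Pnp, a purine salvage enzyme (2.5 ± 0.33), and Bpgm, which makes the red cell's 2,3-bisphosphoglycerate (at least 1.67-fold).

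Also higher at 24 h were Tmbim6 (2.48 ± 0.42), the proton pump subunit Atp6v1e1 (2.11 ± 0.36) and Trim56 (1.84 ± 0.27). Also lower were Serinc1 (-3.34 ± 0.52), Hypk (-2.67 ± 0.54), mitochondrial superoxide dismutase Sod2 (-2.57 ± 0.35) and the mitochondrial ribonuclease Rexo2 (at least 6.15-fold). Sqstm1 was lower by -1.62 ± 0.50 (adjusted p = 0.029), with an adjusted p of 0.050 to 0.087 when any of the 3 wild-type or of mutant arrays 4 and 5 at 24 h was left out and 0.073 without the filter. Tfrc (1.77 ± 0.69, adjusted p = 0.080), Alas2 (-0.07 ± 0.04, 0.28), Slc4a1 (0.25 ± 0.22, 0.43), Hba-a1 (0.05 ± 0.05, 0.43), Bnip3l (0.24 ± 0.10, 0.087), Ulk1 (-0.55 ± 0.36, 0.29; another probe 0.13), Map1lc3b (0.36 ± 0.27, 0.34) and Gabarapl2 (0.40 ± 0.26, 0.27; another probe -0.39) did not pass. Tfrc passed without wild-type or mutant 0 h array 1 (0.036 and 0.040), under median centring (0.021) and with the authors' values (0.019). With the 24 h groups alone Tfrc (4.5e-06), Ulk1 (0.011), Bnip3l (0.014), Slc4a1 (0.033) and Gabarapl2 (0.035) passed. Bnip3l and Slc4a1 turned to -0.12 and -0.18 under median centring and to -0.50 and -0.56 with the authors' values. Gabarapl2 passed under median centring (0.0034) and with the authors' values (0.018), as did Map1lc3b with the latter (0.026).

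Of 60 oxidative phosphorylation genes 15 were lower at 24 h and 9 higher (median -0.10, adjusted p = 0.0177, and 0.909 with an estimated correlation), with Atp5j at -2.16 ± 0.28 and Atp5b at -1.10 ± 0.19; median centring ended the call (0.65), as did leaving out wild-type 24 h array 2 (0.074). Of 15 ubiquitin enzymes 4 were lower and 1 higher (5 and 1 adjusted over the list alone; median -0.62, adjusted p = 0.0445, and 0.909 with an estimated correlation), again not called under median centring (0.27). This call was also lost without wild-type 24 h array 2 or 3, mutant 24 h array 2 or 4 or wild-type 0 h array 2 or 3 (adjusted p 0.051 to 0.092). The ubiquitin ligase Rnf10 went the other way (0.67 ± 0.10), a call that median centring (0.57, adjusted p = 0.088) and the authors' values (0.20, 0.69) ended. Of 14 platelet markers 2 were higher and 0 lower (10 and 0 adjusted over the list alone; median 0.98, adjusted p = 0.0293, and 0.909 with an estimated correlation): the platelet glycoprotein Gp5 (1.10 ± 0.29, 0.011) and Vwf (1.22 ± 0.39, 0.034). The platelet list was not called without wild-type 24 h array 1 (0.37) or 2 (0.11) or mutant 24 h array 2 (0.054). Both gene calls were lost without wild-type 24 h array 1 (0.64, 0.13 and 0.82, 0.20) or array 2 (0.95, 0.083 and 0.98, 0.18), and that of Vwf also without mutant array 3, 4 or 5 (0.061 to 0.066). B cell markers were higher in 1 of 17 (0.73, 0.0800) and neutrophil markers in 2 of 14 (0.80, 0.0800), lists that were called without wild-type 24 h array 1 (0.041 each) or mutant 24 h array 1 (0.038 and 0.045), while 3 of 20 autophagy genes were higher and 2 lower (0.31, 0.488).

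The share of higher calls at 24 h was 51.3%, against 68.7% under median centring and 78.5% with the authors' processed values. The count was 433 without wild-type 24 h array 2, 2104 without the 0 h arrays, 2169 with the 24 h groups alone, 1557 with the authors' values and 2646 with array weights.

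Many differences recurred at all 3 times. Between 0 and 12 h, 976 genes were higher in mutant at both times and 173 lower at both, where independent lists of those sizes would share 566 and 64.8. Between 12 and 24 h the shared genes were 282 and 328, against 143 and 63.1, and between 0 and 24 h 201 and 98, against 142 and 33.3. At all 3 times 177 genes were higher and 92 lower (48.7 and 5.30 for independent lists). Arrays of different times may come from the same animals, so part of the excess may not be independent. Of these genes 141 and 64 passed neither test of a different time course between genotypes.

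**Figure D2:**
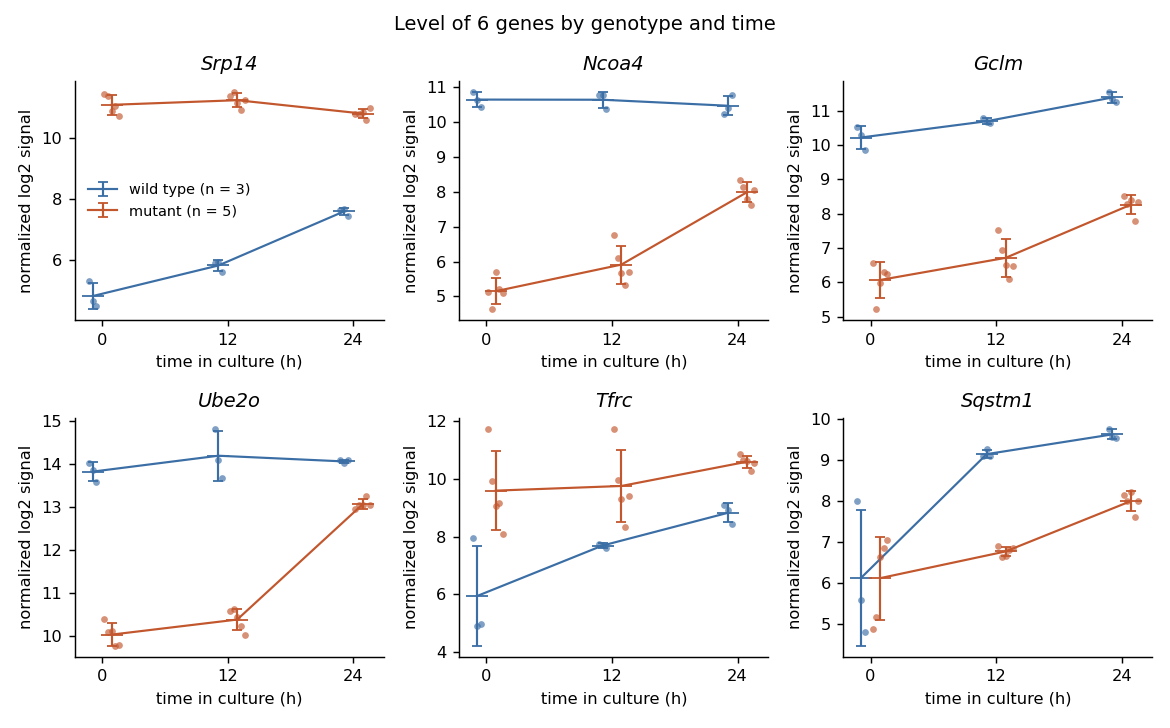
Normalized log2 signal of 6 genes against time in culture, with 1 point per array, lines joining group means and bars of 1 SD, for wild type (n = 3 per time) and mutant (n = 5). Srp14 lay above wild type at all 3 times and Ncoa4 and Gclm below. Ube2o differed by -3.80, -3.82 and -1.0. Tfrc differed by 3.65, 2.06 and 1.77, the last not past the threshold in the main fit, and Sqstm1 by -0.01, -2.37 and -1.62, the earliest not past it.

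The comparison of 12 h with 0 h in wild type asks what changes in culture. Of the genes tested 2166 changed, 1742 up and 424 down. Of the 8 largest fitted rises, 6 were of genes not above background at 0 h and detected at 12 h, given as bounds: the ubiquitin ligase Mkrn1 at least 2.27-fold (adjusted p = 2.4e-07), the transporter Slc16a6 at least 2.36-fold and the transcription factor Cux1 at least 2.27-fold. The actin-severing protein Dstn rose at least 1.97-fold, the superoxide dismutase Sod1 at least 1.96-fold and the glutathione transferase Gstp1 at least 1.89-fold. Sqstm1 rose by 3.01 ± 0.56 (0.00015) and Cmas, which activates sialic acid, by 2.95 ± 0.51 (5.6e-05), but without wild-type 0 h arrays 2 and 3, which left 1 array, these were 1.15 (0.16) and 0.71 (0.072). Both were detected on 1 of 3 arrays at 0 h.

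The largest falls from 0 to 12 h in wild type were to below background: Oser1 at least 12.0-fold, Trp53bp1, a DNA repair protein, at least 18.6-fold, Pcyox1l at least 5.00-fold and Abcf1 at least 5.80-fold. The olfactory receptor Olfr1362 fell at least 4.73-fold, the angiotensin receptor Agtr1b at least 4.62-fold, Setd4 at least 5.67-fold and Prr14l at least 4.49-fold. A second probe went the other way for Trp53bp1 (1.89) and Abcf1 (0.59). Among genes with another probe, the other probe also fell for 15 of 55 that fell (27.3%) and also rose for 318 of 380 that rose (83.7%).

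No gene list was called by camera from 0 to 12 h in wild type, although 2528 genes had an unadjusted p below 0.05 in limma. Of 60 oxidative phosphorylation genes 34 rose and 1 fell (36 and 3 adjusted over the list alone; median 0.85, adjusted p = 0.450), including Atp5j, at least 1.29-fold, and Ndufa12, not above background at 0 h. Of 16 genes of the red cell membrane and skeleton 9 rose and 1 fell (0.80, 0.871), among them Cd47, which protects red cells from macrophages, and Icam4, both not above background at 0 h. Of 42 translation factors 24 rose and 1 fell (0.76, 0.450), and of 35 proteasome subunits 15 and 3 (0.69, 0.874). Of 54 cytosolic ribosomal proteins 11 rose and 3 fell (median 0.07, direction of the test down, 0.450), but both median centring (7.9e-23) and the authors' values (4.3e-09) called this list up, and it was called without wild-type 12 h array 3 (0.018). Among white cell markers, 9 of 17 of B cells rose and 0 fell (1.17, 0.788). Under median centring 7 lists were called and with the authors' values 3. The count of genes was 1023 under median centring, 5911 without the filter, and 1129, with 66.3% rising against 80.4%, without wild-type 0 h arrays 2 and 3 (1 array left). Over all tested genes the median change was 0.36 with the main setting, 0.24 without background correction, 0.07 under median centring and 0.28 with the authors' values.

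From 12 to 24 h in wild type 282 genes changed, 191 up and 91 down, and the gene groups moved apart. Cytosolic ribosomal proteins fell: of 54, 26 fell and 0 rose (35 fell adjusted over the list alone; median -0.81, camera adjusted p = 1.14e-26, and 0.0992 with an estimated correlation), among them Rplp1 (-1.18 ± 0.14, adjusted p = 1.1e-05), Rpl28 (-1.18 ± 0.15, 2.4e-05) and Rpl12 (-1.23 ± 0.17, 5.9e-05). The list was also called down under median centring and with the authors' values, but these 3 genes did not pass with the authors' values (0.36, 0.19 and 0.21). Of 16 red cell membrane genes 3 rose and 0 fell (0.23, adjusted p = 0.00334, and 0.651 with an estimated correlation), with Slc4a1 up by 1.46 ± 0.24. Of 17 globin and heme synthesis genes 4 rose and 0 fell (5 and 2 adjusted over the list alone; 0.17, 0.0471, and 0.675 with an estimated correlation), among them Urod, an enzyme of heme synthesis (2.04 ± 0.31), and Glrx5, which serves iron-sulfur clusters (1.62 ± 0.17). With the animal as a block this list had an adjusted p of 0.0514, and its call was lost without any 1 of 10 arrays (0.0504 to 0.12): wild-type 0 h 1, 12 h 1, 24 h 1 or 2, and mutant 0 h 2 or 4 and 24 h 1, 2, 3 or 5.

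Further lists were called up in wild type from 12 to 24 h. Of 15 ubiquitin enzymes 4 rose and 1 fell (median 0.22, adjusted p = 0.00875, and 0.651 with an estimated correlation), with Fbxo9 up by 2.94 ± 0.33 and Trim10 by 2.62 ± 0.48. Of 35 proteasome subunits 1 rose and 0 fell (0.19, 0.00467, and 0.675 with an estimated correlation): it was the activator Psme4 (2.26 ± 0.36). Of 21 antioxidant genes 4 rose and 0 fell (0.57, 0.000237, and 0.502 with an estimated correlation), with the glutathione peroxidase Gpx1 up by 1.40 ± 0.20. Of 14 platelet markers 3 rose and 0 fell (0.67, 0.000126, and 0.675 with an estimated correlation), a list call lost without wild-type 24 h array 3 (0.29). Its member Gp5 rose at least 1.09-fold, a call lost under median centring (adjusted p = 0.13), with these groups alone (0.057) and without wild-type arrays 24 h 3 (0.052) or 12 h 2 (0.054). The share rising was 67.7%, against 59.5% under median centring and 51.3% with the authors' values. The count was 149, 187 and 170 without wild-type arrays 12 h 3, 12 h 2 and 24 h 2, 817 without the 0 h arrays, 716 with these groups alone, 1500 with array weights and 447 without the filter.

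Over the whole 24 h in wild type 2386 genes changed, 1796 up and 590 down. Fbxo9, a subunit of a ubiquitin ligase, rose at least 8.96-fold (adjusted p = 8.1e-11), Mkrn1 at least 5.10-fold, the splicing protein Snrnp25 at least 5.12-fold, the ATP synthase subunit Atp5j at least 4.38-fold and the mitochondrial transport adaptor Trak2 at least 4.29-fold. Cmas rose by 5.34 ± 0.51 (2e-08), Ranbp10 by 4.02 ± 0.49 and the interferon-induced Ifi27 by 3.87 ± 0.37, all 3 detected on 1 of 3 arrays at 0 h. To below background fell Oser1 (at least 14.9-fold), Pcyox1l (6.19), Olfr1362 (5.85), Agtr1b (5.73), Anapc7 (5.79), Spg20 (5.63) and Prr14l (5.55), while Trp53bp1 fell by 3.92 ± 0.46 and its second probe moved by 1.19.

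The only list camera called from 0 to 24 h in wild type was cytosolic ribosomal proteins, of which 35 fell and 3 rose (median -0.75, adjusted p = 2.57e-12, and 0.976 with an estimated correlation). This direction flips with the scaling: the list was called up under median centring (adjusted p = 0.00049) and with the authors' values (0.00011), where Rpl35 turned from -1.37 ± 0.17 to 1.75 and Rps20 from -1.16 ± 0.16 to 1.94. Rpl7a, at least 1.25-fold higher at 24 h, rose. Not called were oxidative phosphorylation (40 rose, 4 fell; median 1.13, adjusted p = 0.0567), red cell membrane (11 and 1 of 16; 1.39, 0.0567), proteasome (22 and 3; 0.86, 0.236), ubiquitin enzymes (9 and 2; 1.36, 0.287), antioxidant genes (12 and 1; 1.08, 0.458) and platelet markers (10 and 0; 1.58, 0.216). Oxidative phosphorylation was called without wild-type 0 h array 1 (0.012) or 24 h array 3 (0.015), red cell membrane without mutant 12 h array 1 (0.042) and platelet markers without wild-type 24 h array 1 (0.014). Under median centring 10 lists were called and 1130 genes, with the authors' values 6 lists, and with 1 wild-type 0 h array left, without arrays 2 and 3, 1583 genes. The median change of all genes was 0.33, 0.21, 0.07 and 0.21 with the 4 scalings in the order used above, and -0.06, -0.04, -0.01 and -0.08 from 12 to 24 h.

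In mutant reticulocytes 1350 genes changed from 0 to 12 h, 1126 up and 224 down. Mkrn1 rose by 1.64 ± 0.29 (adjusted p = 0.0005), Pink1, a kinase that marks damaged mitochondria, by 1.61 ± 0.43 (0.0084), the RNA-binding protein Ybx3 by 1.75 ± 0.33, Erich5 by 1.92 ± 0.22, the protease Rhbdl2 by 1.90 ± 0.24 and Tmcc2 by 1.57 ± 0.25. Erich5, Rhbdl2 and Pink1 were detected on 3 of 5 arrays at 0 h, and Mkrn1 and Tmcc2 on 4. Oser1 fell by 2.37 ± 0.39 (0.00028) and Trp53bp1 by 2.43 ± 0.36, with its second probe at 0.35. Olfr938 fell at least 3.26-fold, the glycolytic regulator Pfkfb3 at least 2.71-fold and Fxyd4 at least 2.59-fold. Cytosolic ribosomal proteins kept a mean level of 10.54 at 0 and 12 h but were called down relative to other genes, whose median change was 0.25. In this list 2 genes fell and 2 rose, 0 and 0 adjusted over the list alone (median -0.03, camera adjusted p = 0.00699, and 0.991 with an estimated correlation). Neither median centring nor the authors' values called any list, and both turned this one upward. Its member Rpl38 was -0.39 ± 0.11 (0.012), 0.03 and 0.40 under those settings, with a second probe at 0.31, and Rps2 was -0.37 ± 0.13 (0.042), a call lost without any of 6 single arrays (adjusted p 0.062 to 0.11). The share rising was 83.4%, against 49.1% under median centring and 67.7% with the authors' values, which called 663 genes.

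From 12 to 24 h in mutant 1318 genes changed, 610 up and 708 down, and 11 lists were called. Ribosomal proteins fell, 39 of 54 with 3 up (40 and 3 adjusted over the list alone; median -0.84, adjusted p = 8.92e-17, and 0.0922 with an estimated correlation), for example Rpl12 (-1.49 ± 0.13) and Rps21 (-1.12 ± 0.12), but with the authors' values the list was up without being called (0.18), Rpl12 at 0.02 and Rps21 at 0.29. Of 17 globin and heme synthesis genes 6 rose and 2 fell (0.34, 0.00133, and 0.241 with an estimated correlation), Urod by 3.29 ± 0.24 and Glrx5 by 1.2 ± 0.13. Of 8 iron genes 4 rose and 1 fell (0.33, 0.00553, and 0.0596 with an estimated correlation), Ncoa4 by 2.07 ± 0.26 and the iron-sulfur assembly factor Isca1 by 0.90 ± 0.08. Of 16 red cell membrane genes 8 rose and 0 fell (0.82, 1.2e-05, and 0.119 with an estimated correlation), with Slc4a1 up by 1.79 ± 0.19 and the ammonium channel Rhag by 1.43 ± 0.26.

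Ubiquitin enzymes rose in mutant from 12 to 24 h, 10 of 15 with 1 down (median 0.89, adjusted p = 8.33e-07, and 0.0596 with an estimated correlation), Fbxo9 by 2.97 ± 0.26 and Ube2o by 2.69 ± 0.16. Of 35 proteasome subunits 10 rose and 1 fell (0.27, 0.00223, and 0.512), such as Psmd4 (2.0 ± 0.16). Of 21 antioxidant genes 11 rose and 1 fell (14 and 1 adjusted over the list alone; 0.93, 7.84e-07, and 0.0625), such as the reductases Blvrb (1.95 ± 0.18) and Txnrd2 (2.59 ± 0.29). Of 17 genes of the integrated stress response 6 rose and 0 fell (0.42, 0.00224, and 0.0596), among them asparagine synthetase Asns (2.75 ± 0.40) and the heme-regulated kinase Eif2ak1 (1.80 ± 0.26). Of 21 interferon response genes 9 rose and 1 fell (0.32, 0.000516, and 0.159), Rsad2 by 1.85 ± 0.18 and Oasl2 by 2.14 ± 0.29. B cell markers fell, 12 of 17 with 1 up (15 and 1 adjusted over the list alone; -1.23, 0.00041, and 0.557), Cd79b by 1.78 ± 0.37 and Cd79a by 1.23 ± 0.28, where Cd79b did not pass with the authors' values (-0.48, 0.20). Of 14 platelet markers 5 rose and 0 fell (0.54, 0.00156, and 0.561), Gp5 by 2.03 ± 0.25. In each of these brackets the last p is the adjusted p with an estimated correlation. The share rising was 46.3%, against 63.8% under median centring and 88.8% with the authors' values, and the count was 2545 without the 0 h arrays, 2510 with these groups alone and 3273 with array weights.

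Over the 24 h in mutant 2162 genes changed, 1431 up and 731 down. Among the largest rises were Fam214b (4.25 ± 0.26, adjusted p = 1.8e-11), Mkrn1 (4.14 ± 0.29), the glutathione transferase Mgst3 (4.1 ± 0.38), Fbxo9 (4.09 ± 0.26), the chaperone Dnajb2 (4.03 ± 0.43). They also included Pnp (3.94 ± 0.29), Snrnp25 (3.89 ± 0.28) and Asns (at least 8.46-fold, a second probe at 0.70). At 0 h Fam214b and Fbxo9 were detected on 2 of 5 arrays, Mgst3, Pnp and Snrnp25 on 3 and Mkrn1 on 4. The largest falls were those of Gpnmb (at least 13-fold), the plasma cell protein Mzb1 (-2.57 ± 0.40), the transporter Slco4a1 (at least 3.70-fold) and Cerk (-2.45 ± 0.45). They also included the nucleolar protein Npm1 (-2.33 ± 0.41), Trp53bp1 (-2.26 ± 0.36, a second probe at 0.36), the cytokine Mif (-2.24 ± 0.44) and Oser1 (-2.13 ± 0.39), where Npm1 and Mif did not pass with the authors' values (-0.42, 0.17 and -0.24, 0.49).

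Of 16 red cell membrane genes 12 rose and 1 fell over 24 h in mutant (median 1.19, adjusted p = 0.0025, and 0.316 with an estimated correlation). Of 17 globin and heme synthesis genes 10 rose and 0 fell (0.67, 0.00263, and 0.316), Urod by 3.40 ± 0.24. Of 15 ubiquitin enzymes 11 rose and 1 fell (1.49, 0.00263, and 0.307), Ube2o by 3.04 ± 0.16, of 21 antioxidant genes 11 rose and 0 fell (0.90, 0.00485, and 0.316). Of 17 stress response genes 9 rose and 0 fell (0.91, 0.0288, and 0.307), and of 21 interferon genes 12 rose and 1 fell (0.73, 0.00588, and 0.316). Ribosomal proteins were called down (41 fell, 3 rose; -0.94, 1.29e-18, and 0.307), but the list turned upward under median centring (0.95) and was called up with the authors' values (0.017), where Rps2 went from -1.52 ± 0.13 to 0.64 and Rpl12 from -1.50 ± 0.13 to 0.70. Markers of B cells (8 fell, 1 rose; -0.57, 0.0105, and 0.637) and T cells (6 and 1; -0.34, 0.0248, and 0.55) fell and those of platelets rose (8 and 0; 0.82, 0.00949, and 0.637). The B cell call did not hold under median centring (0.069) or with the authors' values (0.17). The share rising was 66.2%, against 82.8% with the authors' values, and 4909 genes were called without the filter. The median change of all genes with the 4 scalings was 0.25, 0.14, 0.10 and 0.12 from 0 to 12 h, -0.12, -0.06, 0.10 and 0.02 from 12 to 24 h and 0.10, 0.06, 0.09 and 0.14 over 24 h.

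**Figure D3:**
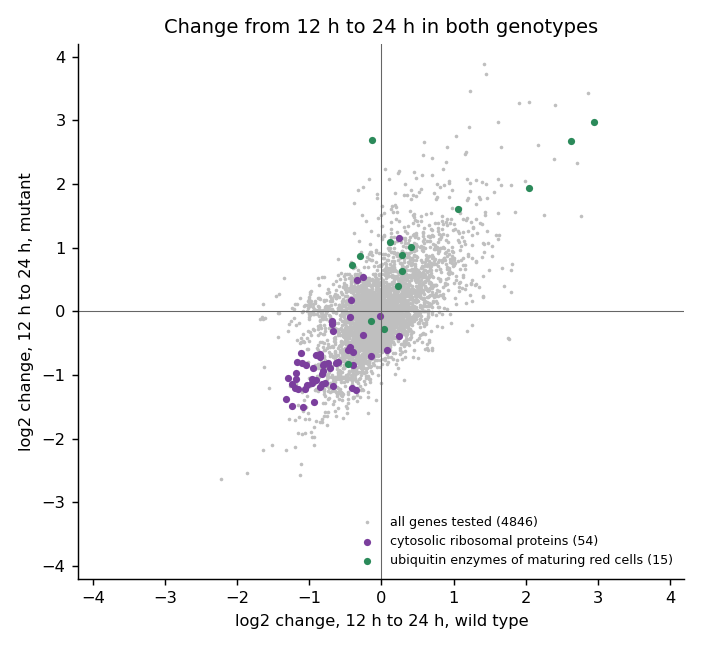
Log2 change from 12 to 24 h in mutant (n = 5 per time) against that in wild type (n = 3), with 1 point per gene for the 4846 genes tested, cytosolic ribosomal proteins in purple and ubiquitin enzymes in green. The ribosomal proteins had medians of -0.81 and -0.84 in wild type and mutant, the mutant value turning upward with the authors' processed values, and the ubiquitin enzymes 0.22 and 0.89.

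Calls of change overlapped between genotypes. From 12 to 24 h 139 genes rose in both and 54 fell in both, where independent lists would share 24.0 and 13.3, and over 24 h 1093 and 311, against 530 and 89.0. From 0 to 12 h the shared genes were 610 and 163, against 405 and 19.6. The 0 h arrays of both genotypes had a median raw signal of 132 to 298, against 38.7 to 44.7 on all later arrays. An array effect common to both genotypes thus cannot be told apart from a shared change since 0 h. In wild type from 0 to 12 h the other probe of a fallen gene fell too in 27.3% of 55. That of a risen gene rose in 83.7% of 380.

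**Figure D4:**
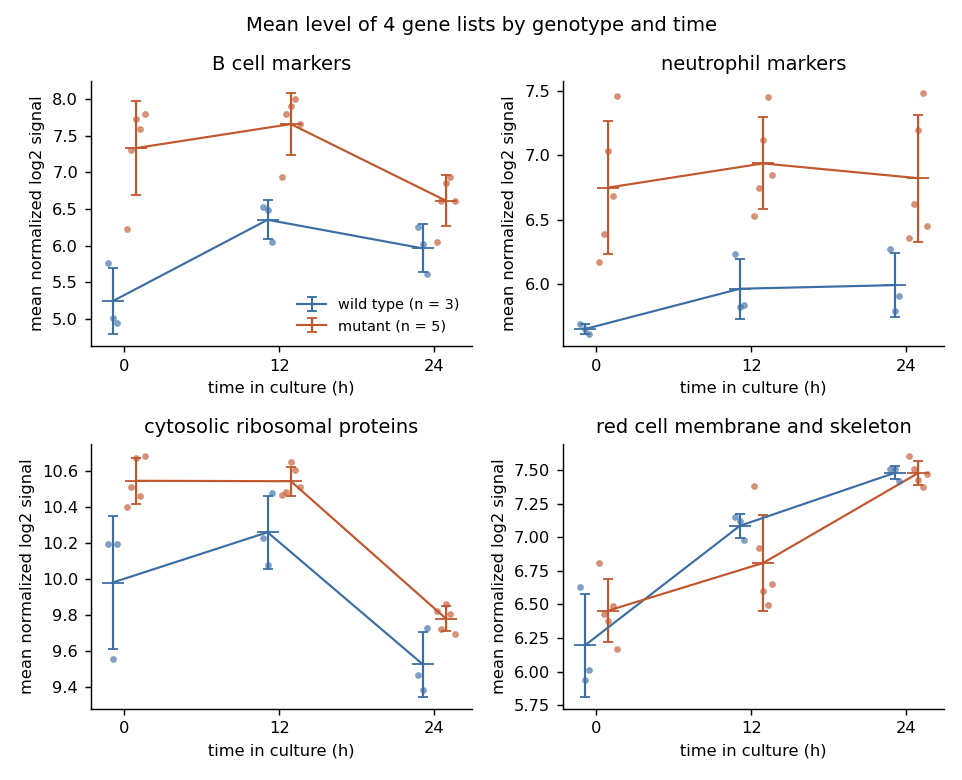
Mean normalized log2 signal of the tested members of 4 gene lists against time in culture, with 1 point per array, lines joining group means and bars of 1 SD, for wild type (n = 3 per time) and mutant (n = 5). B cell markers averaged 7.33, 7.66 and 6.61 in mutant against 5.24, 6.35 and 5.96 in wild type, and the level of ribosomal proteins at 24 h against 0 h changes direction with the scaling.

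The interaction tests asked whether the change in culture differed between genotypes. From 0 to 12 h it differed for 755 genes, 163 with a more positive and 592 with a more negative change in mutant. Snx3, a sorting protein of endosomes, differed by -2.45 ± 0.18 (adjusted p = 9.6e-09), Ptbp3 by -2.15 ± 0.25 and Rpl7l1 by -1.57 ± 0.18, all of them not above background at 0 h in either genotype, detected on all 3 wild-type arrays at 12 h and on 0, 3 and 2 of 5 mutant arrays. Mr1, an antigen-presenting molecule, differed by 3.30 ± 0.32 (6.6e-07), Bloc1s5 by 3.14 ± 0.32 and Rec8 by 2.24 ± 0.25, detected on 3, 3 and 2 wild-type arrays at 0 h and on none at 12 h, so these sizes are fitted values near background. Mr1, Rec8 and Rpl7l1 did not pass under median centring (0.96, 0.48 and -0.94). Of 60 oxidative phosphorylation genes 17 had a more negative change in mutant and 0 a more positive one (19 and 0 adjusted over the list alone; median -0.50, camera adjusted p = 0.00897, and 0.995 with an estimated correlation), Atp5j by -2.36 ± 0.40 and Ndufa12 by -1.75 ± 0.31. Both were not above background in wild type at 0 h, so these sizes are fitted values too.

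From 0 to 24 h the change differed for 797 genes, 227 more positive and 570 more negative in mutant. Ube2o differed by 2.80 ± 0.27 (adjusted p = 2.3e-07), with means of 13.83 and 14.07 in wild type and 10.03 and 13.07 in mutant, and Ubb-ps, a ubiquitin sequence close to that of other ubiquitin genes and so uncertain, by 1.31 ± 0.10. Neither passed with the authors' values (1.22, 0.23 and 0.16, 0.89). Atp5j differed by -4.55 ± 0.40 and Ubl4a, which helps insert membrane proteins, by -2.32 ± 0.21, both not above background in wild type at 0 h. Mr1 differed by 3.25 ± 0.32 and was not above background in wild type at 24 h, so these 3 sizes are fitted values set in part by the background. Eif5 differed by -1.58 ± 0.15. Oxidative phosphorylation had a more negative change in mutant (21 genes more negative, 3 more positive; 23 and 5 adjusted over the list alone; median -0.67, adjusted p = 0.0437, and 0.986 with an estimated correlation), with list means of 6.49 and 7.58 at 0 and 24 h in wild type and of 7.05 and 7.33 in mutant. This call was lost without any 1 of 12 arrays (0.0509 to 0.17): wild-type 0 h 2 or 3, 12 h 1, 24 h 1 or 2, and mutant 0 h 1, 2 or 5, 12 h 1 and 24 h 3, 4 or 5. B cell markers did too (7 more negative, 0 more positive, 10 and 1 over the list alone; -1.68, 0.0348, and 0.986), with list means of 5.24 and 5.96 in wild type, where the list was not called (0.917), and of 7.33 and 6.61 in mutant. The B cell call was not made with the authors' values (0.25), and was lost without any 1 of 8 arrays (0.052 to 0.17): any wild-type 0 h array, wild-type 24 h 1 or 2, and mutant 0 h 2 or 5 and 24 h 1. The globin and heme list had a more positive change in mutant (5 more positive, 1 more negative, 5 and 2 over the list alone; 0.31, 0.0297, and 0.986), a call that neither median centring (0.19) nor the authors' values (0.74) made and that was lost without wild-type 0 h array 1 (0.12) or mutant 0 h array 5 (0.058). The share with a more positive change in mutant was 21.6% from 0 to 12 h and 28.5% from 0 to 24 h, against 5.51% and 40.9% under median centring and 6.57% and 43.4% with the authors' values. The counts were 1262 without wild-type 0 h array 1 from 0 to 12 h and 1321 without mutant 0 h array 1 from 0 to 24 h. From 0 to 24 h they were 301 and 440 under median centring and with the authors' values. The median difference in change over all genes with the 4 scalings was -0.10, -0.07, -0.06 and -0.15 from 0 to 12 h and -0.18, -0.11, 0.00 and -0.05 from 0 to 24 h.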

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

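Of the tests in this part, those of white blood cell RNA, of the yield of the wild-type arrays, of a variant under a single probe, of dilution with genes matched on level and of single probes at 0 h were chosen after the result was seen. A mutant array stood apart from the other 4 of its group, by a gap divided by the group's range, in 39 of the tests made: 6 of 93 on arrays and lists and 33 of 428 on named genes. About 1 in 20 tests does so by chance. The groups of 3 wild-type arrays were not tested. At 0 h the values were 0.803 for the integrated stress response list, 0.724 for Asns, 0.794 for Fcmr, 0.803 for H2-Aa, 0.727 for Mgst3, 0.727 for Mzb1, 0.871 for Olfr1362, 0.738 for Rec8, 0.931 for Rexo2, 0.845 for Ubl4a, 0.767 for Zxda, and 1 for Gpx1 and 1 for Hba-a1, whose other 4 arrays share 1 value. At 12 h they were 0.886 for the tricarboxylic acid cycle and mitochondrial import list, 0.716 for Anp32e, 0.840 for Atp6v1e1, 0.768 for Bnip3l, 0.791 for Cd74, 0.759 for Cd79b, 0.823 for Fam89b, 0.723 for Gtf2e2, 0.769 for Olfr1362, 0.790 for Prr13, 0.798 for Rpl35, 0.833 for Snrnp25, 0.788 for Sod2 and 0.761 for Syngr1. At 24 h they were 0.723 for the median signal, 0.733, 0.763 and 0.748 for the proteasome, cell cycle and platelet lists, 0.713 for Cd79a, 0.762 for Dnajb2, 0.734 for Eif2ak1, 0.756 for Fxyd4, 0.737 for Mif, 0.745 for Ndufv3, 0.722 for Oser1 and 0.717 for Ube2o.

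The change in culture differed between genotypes, by the interaction test, for 755 genes from 0 to 12 h and for 797 from 0 to 24 h. From 0 to 12 h the genes with the smallest p were Snx3 (-2.45), Mr1 (3.30), Bloc1s5 (3.14), Rec8 (2.24), Rpl7l1 (-1.57) and Ptbp3 (-2.15), and the oxidative phosphorylation list had a median of -0.50. From 0 to 24 h they were Ubb-ps (1.31), Atp5j (-4.55), Ubl4a (-2.32), Eif5 (-1.58), Ube2o (2.80) and Mr1 (3.25), with medians of 0.31 for globins and heme synthesis, -0.67 for oxidative phosphorylation and -1.68 for B cell markers. All 6 genes from 0 to 12 h, and Atp5j, Ubl4a and Mr1 from 0 to 24 h, were not above background on any wild-type array at 1 of the 2 times, so their sizes are fitted values. Among the 394 probes without a gene name, which the comparisons do not use, 156 differed between genotypes at 0 h, 197 at 12 h and 80 at 24 h.

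Arrays were split in other ways into groups of the same sizes. For counts of genes, chance is excluded as the whole source at 12 h between genotypes (1 of 56 splits as large, the real one: 2432, highest other 895) and at 24 h (1 of 56; 813, highest other 43), and in mutant from 0 to 12 h (1 of 100; 1350, 908), 12 to 24 h (1 of 100; 1318, 513) and 0 to 24 h (1 of 100; 2162, 1078). At 0 h between genotypes 2 of 56 splits were as large (2060, highest other 2441), and the other one set mutant arrays 3, 4 and 5 against the rest, with all 4 arrays of high background in the group of 5. The 3 further splits with those 4 arrays together called 152, 125 and 70, so background alone does not account for 2441. Mutant arrays 3, 4 and 5 detected 10.5, 12.0 and 17.0% of probes, against 2.17 to 6.34% on the other 0 h arrays. A split by yield thus called more genes than the genotypes did. No count between genotypes can be told apart from an effect of yield. At 12 and 24 h every mutant array detected more probes than any wild-type one. With the background class as a block 1979 genes were called, and within the 4 arrays of high background 1183. For the interactions 1 of 56 splits (755, highest other 568) and 2 of 56 (797, highest other 953) were as large. The 10 splits in wild type are too few for a share under 0.05 (2166, highest other 276; 282, highest other 0; 2386, highest other 256). Of the 16 splits that part all mutant pairs, the highest other counts were 1 from 0 to 12 h and 0 from 12 to 24 h. These 16 are again too few, so chance is excluded for these 2 only by splits that ignore the pairs.

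Counts of called lists are not above what other splits give, so chance is not excluded for them: 22 of 56 splits were as large at 0 h between genotypes (2, highest other 5), 40 at 12 h (3, highest other 11) and 42 at 24 h (3, highest other 8), in mutant 84 of 100 from 0 to 12 h (1, highest other 13), 30 from 12 to 24 h (11, highest other 14) and 11 from 0 to 24 h (10, highest other 11), and for the interactions 18 of 56 (1, highest other 2) and 8 of 56 (3, highest other 9). In wild type the splits are again too few, with counts as large in 10, 3 and 9 of 10 (0, 7 and 1 lists, highest others 5, 7 and 5).

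Some lists of white blood cell markers had higher medians in mutant arrays than 10000 random lists of like brightness. Percentiles at 0, 12 and 24 h were 99.99, 99.99 and 99.93 for B cells, 99.5, 99.71 and 100 for neutrophils, 85.31, 92.36 and 99.99 for monocytes, 87.04, 95.32 and 93.43 for T cells and 37.4, 99.68 and 100 for platelets. Of the 4 white cell lists 2 lay above the random lists at 12 h, 3 at 24 h and never all 4. At 24 h camera called neither B cells nor neutrophils (0.0800 each). Random lists leave out the correlation between markers, and with it estimated no list was called (B cells 0.94 at 12 h, platelets 0.909 at 24 h). A lower yield of wild-type arrays would move markers as it moves other genes of like brightness, but B cell markers minus such genes were higher by 1.2 on the mutant arrays at 12 h (exact two-sided permutation p = 0.0357, the smallest that 3 against 5 arrays can give, adjusted over 18 tests 0.0584), which argues against it as the whole source there, and quantile normalization is argued against by a shift of B cell markers 1.77 times as large under median centring. Minus genes of like brightness, all 4 white cell lists were higher on the mutant arrays at 0 and 12 h (exact permutation p = 0.0357, adjusted 0.0584, each). At 24 h those of B and T cells did not reach this (0.107 and 0.0714). Platelet markers did not separate the genotypes (0.107 at 12 h, 0.214 at 24 h). At 24 h a wild-type array (1.22) topped all mutant ones (at most 1.05). NK cell markers, not among the 4, had percentiles of 85.8, 95.44 and 56.75. RNA of white blood cells in the mutant samples may add to the difference. It cannot be told apart from expression in the reticulocytes, since either would raise the markers. Markers with bright probes, whose signals do not rank abundance between genes, were S100a8 (12.03, 11.64 and 10.77 in mutant, 9.49, 9.45 and 9.40 in wild type) and Cd74 (10.44, 10.62 and 8.97 against 6.69, 8.54 and 7.91), with Lyz2, Cd8b1 and Ppbp at 9.79, 9.02 and 9.11 in mutant at 0 h against 5.81, 6.22 and 6.10, while the T cell marker Cd3e was lower in mutant (7.37, 7.50 and 7.03 against 7.61, 8.62 and 7.54), and no other list held a B cell, T cell, neutrophil or monocyte marker. On all wild-type arrays of some time 7 of 17 B cell, 5 of 14 neutrophil, 2 of 15 T cell and 2 of 11 monocyte markers were detected, and an effect of the genotype was not tested apart from these.

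Of the genes that differed between genotypes in the same direction at 0, 12 and 24 h, 205 passed neither interaction test, which does not show that their differences were equal in size. Segments of another strain near the mutated gene would put neighbours along a chromosome in the set, but 16 genes had one, against a median of 16 in random sets (58.19% of which had as many), which argues against this for the set as a whole. Dilution of red cell RNA would lower red cell genes alike. For this, 21 red cell membrane and heme genes were each matched to a lower gene on its wild-type level (medians 7.84 and 7.84). At 24 h they had a median of -0.12 (-0.24 to 0.19), against -1.24 (-1.38 to -0.85) for the matched genes. The 64 lower genes were chosen in part by this same difference, so the gap is partly built in and cannot decide. The 21 red cell genes, taken whether called or not, showed no shared fall (3 called lower and 3 higher). A variant under a single probe cannot be told apart for the set, since the other probe of 53 genes moved by a median of 0.615 times the probe used (0.450 to 0.699) with the same sign in 50, and most genes have 1 probe. An effect of the genotype stays open and was not tested apart from these.

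More genes rose than fell from 0 to 12 h in wild type. A higher background at 0 h was predicted to hide dim genes most. The share rising among called genes was instead lower in the dimmest of 3 equal classes (62.2%) than in the brightest (95.8%), by -33.6 points. But wild-type arrays detected only 558 to 1187 probes at 0 h and 1265 to 1700 at 12 h. Dim genes could be below background at both times, and bright ones hidden at 0 h. The test thus cannot decide, and background at 0 h stays open. Signal of single probes on the 0 h arrays may account for falls: the other probe of a fallen gene fell too in 27.3% of 55, while that of a risen gene rose in 83.7% of 380. A low yield of wild-type arrays 2 and 3 at 0 h also stays open, since without them 1129 genes changed and 66.3% of them rose, with 1 wild-type 0 h array left that was assumed to vary like the other groups. A change in the cells with time stays open as well and was not tested apart from these.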

How the results depend on the processing

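Of the settings in this part, those without the 0 h arrays, without wild-type 0 h arrays 2 and 3, with the background class as a block, within the arrays of high or low background and with sign changes within pairs were chosen after the data were seen. Of 3022 alternatives for 238 named gene results (left-out arrays counted for the lowest and highest value and each change of call), 2810 kept direction and side of the threshold, 125 lost the call, 49 gained it, 24 moved without a call and 14 reversed. The losses came from leaving out 1 array (52), the authors' values (22), median centring (17), leaving out wild-type 0 h arrays 2 and 3 (8), no filter (7) and other settings (19). No background correction and the mean of a gene's probes moved no count by more than 1.5 times. Below, 0-12, 12-24 and 0-24 stand for times of culture in hours, and where a construction does not show it (fewer genes or arrays), the cause was not tested.

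Median centring called 1023 genes in wild type 0-12, 1130 in wild type 0-24, and 472 and 301 in the interactions 0-12 and 0-24, and 7 lists at 0 h, 7 at 24 h, 7 in wild type 0-12, 10 in wild type 0-24, 0 in mutant 0-12 and 4 in the interaction 0-12. The authors' values called 1172 genes at 12 h, 1557 at 24 h, 663 in mutant 0-12 and 440 in the interaction 0-24, and 1 list at 0 h, 5 at 12 h, 3 in wild type 0-12, 6 in wild type 0-24, 0 in mutant 0-12 and 4 in the interaction 0-12. Without the filter there were 3334 genes at 0 h, 5911, 447 and 7148 in wild type 0-12, 12-24 and 0-24, 2896 and 4909 in mutant 0-12 and 0-24 and 1229 in the interaction 0-12. Probes detected in all 24 arrays are few, and called were 137, 133 and 113 between genotypes, 6, 110 and 124 in wild type, 24, 128 and 134 in mutant and 3 and 48 in the interactions. Array weights called 4009 at 12 h, 2646 at 24 h, 1500 and 3273 in wild type and mutant 12-24 and 1464 and 1368 in the interactions. A fit of only the groups compared called 593 at 0 h, 2169 at 24 h, 716 and 2510 in wild type and mutant 12-24 and 437 and 421 in the interactions. An estimated correlation called 0 lists with camera in each of the 10 comparisons that had called any. Without the 0 h arrays 2104 genes and 1 list were called at 24 h, and 817 and 2545 genes in wild type and mutant 12-24, among them 807, 279 and 1304 of those called with them. Without wild-type 0 h arrays 2 and 3, and within the low-background arrays, 1 wild-type 0 h array remained, assumed to vary like the other groups. Without those 2 arrays the counts were 1286 at 0 h, 1129 and 1583 in wild type 0-12 and 0-24 and 473 in the interaction 0-12, and 1183 within the 4 arrays of high background. At a detection p below 0.05 the difference in detected share was 9.42 points at 0 h, -8.01 in mutant 12-24 and -0.31 in wild type 12-24, reversed from 1.60. With sign changes within the pairs of arrays, the replicate block for this share, the change of 11 points in mutant 0-12 had an exact p of 0.0625, the smallest that 5 pairs can give.

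Leaving out each array in turn gave 1641 to 2442 genes at 0 h, 1310 to 2726 at 12 h, 433 to 1095 at 24 h, 1777 to 2378, 149 to 375 and 2088 to 2586 in wild type 0-12, 12-24 and 0-24, 983 to 1714, 890 to 1619 and 1908 to 2353 in mutant, and 527 to 1262 and 573 to 1321 in the interactions. Counts moved by over 1.5 times at 12 h without wild-type 12 h array 2 (1541) or 3 (1310), at 24 h without wild-type 24 h array 2 (433), in wild type 12-24 without wild-type arrays 12 h 2 (187), 12 h 3 (149) and 24 h 2 (170), and in the interactions without wild-type 0 h array 1 (1262) and mutant 0 h array 1 (1321). Lists numbered 1 to 4 at 0 h (1 without wild-type array 2 or mutant arrays 3 or 5, 4 without wild-type array 3 or mutant array 2), 2 to 4 at 12 h, 0 to 5 at 24 h (0 without wild-type array 2, 5 without mutant array 1, 1 without mutant array 2), 0 to 1, 6 to 9 and 1 to 2 in wild type (1 in 0-12 without 12 h array 3; 2 in 0-24 without wild-type 0 h array 1, 24 h array 1 or 3 or mutant 12 h array 1), 1 to 2, 11 to 13 and 10 to 10 in mutant (2 in 0-12 without mutant 0 h array 3 or 5 or 12 h array 1), 1 to 1 in the interaction 0-12 and 0 to 4 in the interaction 0-24 (0 without mutant 0 h array 5; 1 without any wild-type 0 h array, wild-type 24 h array 1 or 2 or mutant 0 h array 2).

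Reversed genes were Bnip3l at 0 h (0.084, authors' values), Alas2 at 12 h (-0.28, median centring; -1.01, authors' values), Rpl35 (1.75, authors' values) and Rps20 (0.15 and 1.94) in wild type 0-24, Rpl38 (0.029 and 0.40) and Rps2 (0.29, authors' values) in mutant 0-12, Rpl12 (0.020) and Rps21 (0.29) in mutant 12-24, Rps2 (0.64) and Rpl12 (0.70) in mutant 0-24 and Slc25a39 in the interaction 0-24 (-0.14), the last 5 with the authors' values. With the animal as a random block counts were 2086, 2459 and 831 between genotypes and 402 and 1642 in wild type and mutant 12-24, and the only list call it changed was globins and heme synthesis in wild type 12-24 (adjusted p = 0.0514). It changed the call of no named gene. With the replicate number shared by both genotypes 1624, 1689 and 559 genes were called between genotypes, although the numbers do not pair genotypes. A chip or slide effect was not run, since the files give no chip identity. Signal over background limited which genes could be measured: 235 of 25697 probes were above background on all 24 arrays.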

Other observations

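The test of a shared stage of maturation in this part was chosen after the result was seen. Values of further lists, mutant against wild type at 0, 12 and 24 h, are given as numbers higher and lower, medians and camera adjusted p of the main setting. Genes of red cell identity had no called list: of 17 globin and heme synthesis genes 4 were higher and 6 lower, 5 and 4, and 4 and 0 (medians -0.05, 0.04 and 0.05; 0.0723, 0.657 and 0.603), of 8 iron genes 4 and 2, 1 and 2, and 1 and 2 (0.19, 0.06 and 0.09, with means of -0.26, -0.46 and -0.11; 0.221, 0.235 and 0.311), of 13 erythroid transcription factors and receptors 5 and 1, 4 and 3, and 2 and 2 (0.32, -0.07 and 0.12; 0.884, 0.657 and 0.823), and of 16 red cell membrane genes 4 and 2, 3 and 5, and 3 and 3 (0.02, -0.11 and 0.05; 0.481, 0.230 and 0.603). Of 21 antioxidant genes 6 were higher and 4 lower, 5 and 5, and 5 and 2 (0.13, 0.24 and 0.22; 0.460, 0.412 and 0.800), of 15 glycolysis genes 9 and 3, 7 and 3, and 1 and 0 (0.90, 0.41 and 0.12; 0.929, 0.931 and 0.603), and of 20 genes of the tricarboxylic acid cycle and mitochondrial import 7 and 0, 7 and 2, and 1 and 0 (0.30, 0.35 and 0.30; 0.696, 0.850 and 0.761). At 0 h 2 of 10 mitophagy regulators were higher and 2 lower (0.19, 0.745). The globin and heme list was called at 0 h when mutant 0 h array 1 (camera adjusted p = 0.049) or 2 (0.044) was left out.

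Stress and signalling lists were not called between genotypes either. The medians at 0, 12 and 24 h were 0.33, -0.02 and 0.43 for 17 integrated stress response genes (camera adjusted p = 0.745, 0.657 and 0.395), 0.63, 0.58 and 0.55 for 11 heat shock genes (0.529, 0.814 and 0.395), 0.55, 0.38 and 0.17 for 15 p53 targets (0.696, 0.915 and 0.905), 0.23, 0.27 and 0.07 for 12 cell cycle genes (0.703, 0.657 and 0.311), 0.81, 0.76 and 0.56 for 16 immediate early genes (0.935, 0.929 and 0.823), 0.37, 0.41 and 0.45 for 14 inflammatory genes (0.745, 0.688 and 0.488), 0.23, 0.13 and 0.22 for 21 interferon response genes (0.850, 0.608 and 0.529) and 0.93, 0.81 and 0.26 for 6 NK cell markers (0.760, 0.657 and 0.842). The lists of eosinophil, basophil and mast cell markers (1 tested gene) and of endothelial and stromal markers (2) were too small to test.

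A hypothesis was that mutant cells may be at an earlier stage of the same program of maturation than wild type. Differences between genotypes at 0 h would then run against the wild-type change from 12 to 24 h across genes. The correlation was 0.038 over 4846 genes, and that of the difference at 24 h with the mutant change from 0 to 12 h was -0.01, so the prediction was not met, and the data cannot tell whether the stage differed.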
